A study of Arabidopsis thaliana with 25 samples.

How the data were processed

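RNA from 25 samples of whole Arabidopsis Col-0 seedlings was measured on one-colour Cy3 arrays, 1 array per sample, with 100 ng of RNA labelled for each. Per the labels the seedlings were aged 10 days, grew in liquid medium before treatment and took up 100 µM RL or water, both with 0.5% ethanol, through the roots. The spot intensity values are those that Agilent Feature Extraction 11.5.1.1 wrote, per the file headers, with the background subtracted and spatial trends removed within each array and no scaling between arrays. The median pixel intensity of each spot and of its local background was deposited beside them without processing. Other values in the deposited array files are flags of 0 or 1 per spot, set by Feature Extraction for saturation, outlier spots and signal well above background. A table of log2 values was deposited by the authors for 34020 of 43603 probes. The labels name limma for it without a version, and its column medians of 9.447 to 9.4608 are nearly the same in every array, as quantile normalization leaves them.

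Each array held 45220 spots, 43803 of them not controls. Probes were matched to loci through their RefSeq transcript accession, which gave 34348 of 43603 probes and 25410 loci. No genome sequence was at hand, so genes are named by locus code and symbol without coordinates. The log2 processed signal of each array was set relative to its 75th percentile, spots with an outlier flag were left out and spots of the same probe were averaged. A probe was kept when it was well above background on all 5 arrays of at least 1 group, which left 31761 probes. The brightest kept probe stood for each locus, and 19939 loci were tested. Of these 5955 had more than 1 kept probe.

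Group means were fitted with limma 3.58.1 in R 4.3.3 with moderated variances, and 5 contrasts were taken: RL against water at 1 h and at 3 h, the difference between these effects, and water at 1 h and at 3 h against 0 h. Both water contrasts use the 0 h samples and the RL contrasts use the water samples, so overlaps between such contrasts are not given. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, with a second count at a change of at least 1 on the log2 scale. A gene is said to have risen or fallen only when it passed. Where the probe was below background on all 5 arrays of 1 group, the fold is a lower bound: the other group's mean was set against the level at which spots of those arrays began to be called well above background, and the words at least mark it. No fold is given where both groups were below background.

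Lists of genes were fixed before the data were examined, 12 as families by symbol and 26 by function with 507 entries. Of these 24 were left out because locus and symbol did not belong together in the reference, and 14 were paired but not tested, PR1 among them because its probe stayed near background. ACT2 had no matched probe. List counts are given over all genes and adjusted over the list alone. The set test was limma's camera with a preset correlation of 0.01, adjusted over 190 tests, and it was repeated with a correlation estimated for each list, which kept 4 of 106 calls: the rapid immune, auxin and ERF lists with RL at 1 h and the glycosyltransferases in water at 3 h. In 34 of 190 tests a list's median, mean and test differed in sign, 0 of them past the threshold. For RL at 1 h they were the abscisic acid, phenylpropanoid, photosynthesis, cell cycle, sphingolipid and MYB lists, and at 3 h the clock, iron and low oxygen lists.

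The genes to name were also set before the data were examined. For each RL contrast they were the 10 largest rises and the 10 largest falls among genes past the threshold that changed the same way in all 5 experiments and were above background on all 5 arrays of at least 1 group. For the other contrasts they were the 5 largest of each. A panel of 13 genes and, in each list, up to 4 members with the smallest adjusted p were added. Names outside this rule are said to have been chosen after their values were seen.

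The labels number the experiments, and samples of the same number were checked for likeness. The mean correlation of their deviations from the group means was 0.123 within experiments and -0.0308 between them, and the estimated block correlation was 0.134. The fit reported has no block, and fits with the experiment as a fixed or a random term were run beside it. The file headers give 7 slides and 2 scan dates, with 15 and 10 arrays, 3 and 2 of each group. Fits with slide or scan date as a block and fits within each scan date are given beside the results. One gene that belongs to the lists tested is not reported here by itself.

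Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, scaling to the median, the authors' deposited values, no filter on dim probes, a filter on all 25 arrays, the mean of a gene's probes, another variance model, only the groups of a contrast, the blocks named above, each sample left out in turn and stricter thresholds. Mean pixel signals were not used here, and normexp was run on the median signals in their place. Other alternatives were chosen after the data were seen. They were normexp with quantile normalization, normexp without spots of flagged local background, each scan date alone, and the counts without both 0 h replicate 5 and water 1 h replicate 4. The set test with slide or scan date as a block, or without CDPK-related kinases in the CRK family, was chosen then too.

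The steps were tested on simulated data with changes of 0.5, 1 and 2 on the log2 scale added to a part of 19908 genes. With RL at 1 h 56.7%, 91.0% and 97.7% of the added changes were called, with RL at 3 h 67.2%, 83.7% and 97.7%, for the difference between the effects 47.0%, 81.9% and 96.6%, in water at 1 h 65.7%, 88.1% and 100%, and in water at 3 h 59.7%, 85.1% and 97.0%. Of the calls made 5.06% to 6.84% were false. A shift added to the heat shock list gave adjusted p = 1.54e-15, and 1 other list of 190 passed. The simulated noise was drawn independently for each gene. It therefore cannot show how often lists of genes that move together pass by chance in the real samples. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.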

Results

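Transcript levels were measured on 25 one-colour arrays in whole Arabidopsis thaliana Col-0 seedlings aged 10 days that took up 100 µM mono-rhamnolipids through the roots. Mono-rhamnolipids (RL) are glycolipids that the bacterium Pseudomonas aeruginosa secretes. The RL were given in 0.5% ethanol. Control seedlings received water with the same share of ethanol. Seedlings were harvested before treatment (0 h), 1 h and 3 h after water, and 1 h and 3 h after RL, in 5 independent experiments, so each of the 5 groups held 5 samples. One sample of the RL 1 h group, replicate 1, is called water in its source name and RL in all its other labels. On the first principal component it lay at 34.95, inside the range of the other RL 1 h samples.

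The 75th percentile of the processed signal ran from 866.3 to 1846 across the arrays over a median local background of 25 to 31, and no spot was saturated. Between 69.43% and 77.54% of the spots were well above background. The RL 3 h arrays were dimmer, with a 75th percentile of 1075 ± 146.8 (mean ± SD, n = 5) against 1437 ± 142.3 for water at 3 h, and with 71.13% ± 1.31 against 74.72% ± 2.13 of spots well above background. Replicates correlated across genes with r from 0.978 to 0.995. The first principal component held 68.2% of the variance and the next 10.3%. On the first component the RL 3 h samples lay at 115 to 125.5, the RL 1 h samples at 21.78 to 41.17, and the water and 0 h samples from -68.7 to -32.55. The number of arrays per group limits the precision of every value.

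Changes are differences between group means on the log2 scale, given ± SE where an error is printed, with 5 samples in each group. Adjusted p of genes come from limma over 19939 genes, and those of gene lists from its set test over 190 tests. Where a list's count is followed by no second count, the count adjusted over the list alone was the same. Where the lower group was well above background on only 1 or 2 of its 5 arrays the background limits the log2 value, and for the largest rises and falls the lower bound of the fold is given instead.

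Which transcripts had changed 1 h after RL was asked by setting the RL 1 h samples against the water 1 h samples. Of the 26 measured members of the rapid immune list 25 rose, with a median change of 3.45. WRKY33 (AT2G38470), a regulator of camalexin synthesis, rose by 3.94 ± 0.253 (adjusted p = 1.89e-11), and PROPEP3 (AT5G64905), which encodes the precursor of a danger peptide, rose by 4.76 ± 0.282 (adjusted p = 4.43e-12). Among the largest falls were RHS19 (AT5G67400), a peroxidase, which fell by 5.45 ± 0.343 on the log2 scale, and XTH14 (AT4G25820), a cell wall enzyme, which fell by 5.29 ± 0.417. In total 5302 of 19939 genes differed, 2071 higher and 3231 lower with RL. Of these 1035 and 542 changed by at least 2-fold.

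Among the largest rises at 1 h was that of AT1G22810, an ERF family factor (adjusted p = 1.45e-14). Its probe was not well above background in any water sample, so the rise was at least 126-fold. By the same reasoning AT4G37710, a VQ motif protein, rose at least 58.2-fold, the peroxidase AT1G14550 at least 43.4-fold, AT4G37290 at least 38.4-fold, AT5G57510 at least 27-fold and AT2G23270 at least 23.3-fold. The glutathione transferase GSTU12 (AT1G69920) rose 168-fold and the phloem protein PP2-B13 (AT1G56240) 115-fold. AT2G44578 rose at least 66.2-fold, and AT3G02840 rose by 6.45 ± 0.335. Among the largest falls was that of the root glucosidase BGLU35 (AT1G51470) at -5.73 ± 0.445 (adjusted p = 4.76e-10). AT1G19900 fell at least 16.5-fold. AT5G04960, a pectin methylesterase, fell at least 21.2-fold. AGP3 (AT4G40090), an arabinogalactan protein, stood at -4.71, and the peroxidases AT1G05240 and AT4G26010 stood at -4.96 and -4.44. Of 2 CAP family proteins AT5G57625 changed by -4.67 and AT4G30320 fell at least 17.2-fold.

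In the rapid immune response list at 1 h 25 of 26 members rose (26 adjusted over the list alone), with ERF6 (AT4G17490) at 4.97, PER4 (AT1G14540) at 5.24, PUB24 (AT3G11840) at 3.27 and ATL6 (AT3G05200) at 1.81, and adjusted p = 5.37e-40, or adjusted p = 0.0262 with an estimated correlation. The member that did not pass over all genes was FRK1 (AT2G19190), a flagellin-responsive kinase, with a change of 1.21 ± 0.572 (adjusted p = 0.126). Among 31 receptors and signalling genes 21 rose (23 adjusted over the list alone) and 0 fell, with PEPR2 (AT1G17750) at 2.65, LYK5 (AT2G33580) at 3.1 and CPK28 (AT5G66210) at 1.83. Their median was 0.70, with adjusted p = 7.59e-18, or adjusted p = 0.0964 with an estimated correlation. Within it the kinase MPK3 (AT3G45640) rose by 2.46 ± 0.12 and the oxidase RBOHD (AT5G47910), which makes the immune oxidative burst, by 2.40 ± 0.206. Outside the list as tested, SD1-29 (AT1G61380), the receptor kinase LORE that senses bacterial 3-hydroxy fatty acids, rose by 0.61 ± 0.174 (adjusted p = 0.0104). In the touch and calcium binding list 9 of 10 rose, with CML37 (AT5G42380) at 5.87, AT1G76640 at 5.71, TCH4 (AT5G57560) at 3.02 and TCH3 (AT2G41100) at 2.87. Its median was 2.31, with adjusted p = 2.74e-12, or adjusted p = 0.0929 with an estimated correlation.

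In the ethylene pathway at 1 h 14 of 29 rose and 3 fell (15 and 4 adjusted over the list alone), with ERF13 (AT2G44840) at 5.30, ERF5 (AT5G47230) at 3.43 and ERF-1 (AT4G17500) at 2.58. The list as a whole had adjusted p = 1.7e-10, or adjusted p = 0.0965 with an estimated correlation. In the salicylic acid pathway 13 of 24 rose and 2 fell, with the receptor NPR3 (AT5G45110) at 2.31, PAD4 (AT3G52430) at 1.76 and CBP60G (AT5G26920) at 2.90, and adjusted p = 2.69e-06, or adjusted p = 0.29 with an estimated correlation. EDS16 (AT1G74710), the isochorismate synthase of salicylic acid formation, stood at -0.03 ± 0.247 (adjusted p = 0.942). In the jasmonate pathway 14 of 30 rose and 2 fell, with LOX4 (AT1G72520) at 3.99, AOC3 (AT3G25780) at 2.95 and MYC2 (AT1G32640) at 1.43. The set test gave adjusted p = 1.15e-06, or adjusted p = 0.276 with an estimated correlation. The defensin PDF1.2 (AT5G44420) stood at -0.37 ± 0.25 (adjusted p = 0.302). In the auxin response 8 of 17 rose (9 adjusted over the list alone) and 0 fell, with IAA2 (AT3G23030) at 1.29, SAUR9 (AT4G36110) at 2.1 and IAA19 (AT3G15540) at 1.13, and adjusted p = 1.43e-05, or adjusted p = 0.0262 with an estimated correlation. Of 23 abscisic acid and water stress genes 3 rose and 2 fell (adjusted p = 0.212), the rises being CYP707A3 (AT5G45340) at 2.65, CBF2 (AT4G25470) at 2.83 and CBF1 (AT4G25490) at 1.45. The falls in these lists, all but ABF3 (AT4G34000) named after their values were seen, were small for the most part. For ethylene they were ORA59 (AT1G06160), ETR2 (AT3G23150) and EIN2 (AT5G03280), at -0.63, -0.41 and -0.37. For salicylic acid they were UGT76B1 (AT3G11340) and AT4G10500, at -0.89 and -1.83, and for jasmonate COI1 (AT2G39940) and JAR1 (AT2G46370), at -0.34 and -0.20. For abscisic acid they were ABF3 and ABI2 (AT5G57050), at -0.30 and -0.28.

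In the tryptophan, camalexin and indole glucosinolate list at 1 h 15 of 26 rose and 1 fell, with IGMT2 (AT1G21120) at 3.12, MYB51 (AT1G18570) at 3.62 and CYP81F2 (AT5G57220), which modifies indole glucosinolates, at 3.85. The list as a whole had adjusted p = 4.64e-10, or adjusted p = 0.144 with an estimated correlation. The fall was that of MYB34 (AT5G60890), named after its value of -1.17 was seen, and PAD3 (AT3G26830), the last enzyme of camalexin synthesis, stood at 0.86 ± 0.382 (adjusted p = 0.102). In the xenobiotic detoxification list 14 of 25 rose and 0 fell, with the transporter ABCG40 (AT1G15520) at 3.31, GSTU11 (AT1G69930) at 4.28 and CYP81D8 (AT4G37370) at 3.62, and adjusted p = 1.05e-09, or adjusted p = 0.104 with an estimated correlation. In the mitochondrial stress list 4 of 6 rose, BCS1 (AT3G50930) by 3.97, AOX1A (AT3G22370), the alternative oxidase, by 1.66, AOX1D (AT1G32350) by 1.85 and NAC13 (AT1G32870) by 0.56, with adjusted p = 0.00109, or adjusted p = 0.194 with an estimated correlation. In the heat shock list 8 of 13 rose, or 5 in the deposited values of the authors, and 0 fell, with HSFB2A (AT5G62020) at 2.46, HSP21 (AT4G27670) at least 2.09-fold higher and DREB2A (AT5G05410) at 1.44. The set test gave adjusted p = 3.41e-07, or adjusted p = 0.15 with an estimated correlation. In the aliphatic glucosinolate list 8 of 15 fell (9 adjusted over the list alone), with MYB28 (AT5G61420), their main regulator, at -0.76, IPMI1 (AT3G58990) at -1.04 and GSTF11 (AT3G03190) at -1.16, and adjusted p = 0.00291, or adjusted p = 0.342 with an estimated correlation. In the flavonoid and anthocyanin list 6 of 12 fell (7 adjusted over the list alone), with AT1G56650, the anthocyanin regulator PAP1, at -1.46 and MYB111 (AT5G49330) at -0.92. The list as a whole had adjusted p = 0.0149, or adjusted p = 0.438 with an estimated correlation.

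Of 14 root markers 1 rose and 5 fell at 1 h (1 and 8 adjusted over the list alone), with adjusted p = 0.0252, or adjusted p = 0.442 with an estimated correlation and adjusted p = 0.0647 with slide as a block. The root hair genes PRP3 (AT3G62680), EXPA7 (AT1G12560) and SHV2 (AT5G49270) fell by 3.76, 3.49 and 1.80 on the log2 scale, the phosphate transporter PHT1;1 (AT5G43350) changed by -2.48, and the Casparian strip protein CASP1 (AT2G36100) by -0.45. The rise was that of MYB36 (AT5G57620), an endodermal regulator, at 0.77, and CASP1 and MYB36 were named after their values were seen. The iron uptake genes IRT1 (AT4G19690) and FRO2 (AT1G01580) fell, at least 9.65-fold and by 2.60 on the log2 scale, and PYE (AT3G47640) rose by 0.92. The iron list as a whole, with 1 of 12 up and 2 down, did not pass (adjusted p = 0.982). For the remaining fixed lists at 1 h the set test did not pass. Of 33 photosynthesis (shoot) genes 0 rose and 0 fell by limma, with 0 past an unadjusted p of 0.05 (list adjusted p = 0.695). Of 19 phenylpropanoid and lignin genes 2 rose and 4 fell (0.884). In the unfolded protein response 1 rose and 3 fell of 14 (0.602; 2 and 8 adjusted over the list alone), and among 22 clock genes 1 rose and 4 fell (0.455). Of 15 cell cycle genes 1 fell (0.884; 0 adjusted over the list alone), of 14 sterol synthesis genes 1 fell (0.181), of 14 sphingolipid genes 2 rose (0.332). Of 12 low oxygen genes 1 rose and 1 fell (0.204). Of 5 sugar starvation genes 2 rose (0.115; 2 up and 1 down adjusted over the list alone). Of 8 reference genes 1 fell (0.695). The phenylpropanoid members past the threshold were AT1G80820 at 4.22 and PAL2 (AT3G53260) at 0.41 against AT3G13610 at -2.30, AT4G36220 at -0.37, ATCAD4 (AT3G19450) at -0.21 and OMT1 (AT5G54160) at -0.20. In the unfolded protein response they were BZIP60 (AT1G42990) at 1.43 against CNX1 (AT5G61790), ATERDJ3B (AT3G62600) and CRT1b (AT1G09210) at -0.30, -0.25 and -0.21. Among clock genes they were BOA (AT5G59570) at 1.15 against AT1G18330 at -0.76, ELF4 (AT2G40080) at -0.69, PRR3 (AT5G60100) at -0.42 and FKF1 (AT1G68050) at -0.35. The cell cycle gene was CYCD3;1 (AT4G34160) at -0.23, the sterol gene SMT3 (AT1G76090) at -0.35 and the reference gene PEX4 (AT5G25760) at -0.22. The sphingolipid genes AtIPCS2 (AT2G37940) and LOH2 (AT3G19260) stood at 1.01 and 0.53. ERF71 (AT2G47520) at 3.77 and AT3G10040 at -0.67 were the low oxygen genes, and ASN1 (AT3G47340) and DIN2 (AT3G60140) at 1.45 and 1.38 those of sugar starvation. ATCAD4, OMT1 and FKF1 were named after their values were seen.

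Among gene families at 1 h the ERF factors had the lowest adjusted p of the set test, with 16 of 25 up and 2 down (17 and 3 adjusted over the list alone), TDR1 (AT3G23230) at least 70.4-fold higher and adjusted p = 3.99e-15, or adjusted p = 0.0262 with an estimated correlation. The 2 falls, CRF8 (AT1G71130) at -0.48 and ERF38 (AT2G35700) at -0.49, were named after their values were seen. Of 60 WRKY factors 28 rose and 7 fell (28 and 8 adjusted over the list alone), with WRKY40 (AT1G80840) at 5.08 and WRKY53 (AT4G23810) at 1.91, and adjusted p = 9.79e-10, or adjusted p = 0.163 with an estimated correlation. Of 20 U-box ubiquitin ligases 13 rose and PUB8 (AT4G21350), named after its value of -0.39 was seen, fell, with PUB23 (AT2G35930) at 3.61 and PUB22 (AT3G52450) at 2.60. The set test gave adjusted p = 9.93e-11, or adjusted p = 0.0929 with an estimated correlation. Of 28 genes in the family of cysteine-rich receptor-like kinases, built by the symbol CRK, 14 rose and 5 fell, with CRK10 (AT4G23180) at 1.72 and CRK31 (AT4G11470) at least 5.07-fold higher, and adjusted p = 5.37e-06, or adjusted p = 0.29 with an estimated correlation. The falls, named after their values were seen, were CRK25 (AT4G05200) at -2.37, CRK27 (AT4G21230) at -1.71, CRK26 (AT4G38830) at -1.03, AT2G46700 at -0.38 and CRK1 (AT2G41140) at -0.28. The last 2 are CDPK-related kinases that share the symbol, and without them 14 of 26 rose and 3 fell (adjusted p = 1.87e-07, or adjusted p = 0.258 with an estimated correlation). Of 10 wall-associated kinases 6 rose and WAKL1 (AT1G16120), named after its value of -0.69 was seen, fell, with WAKL10 (AT1G79680) at 3.54 and WAKL2 (AT1G16130) at 2.31. The list as a whole had adjusted p = 6.96e-05, or adjusted p = 0.139 with an estimated correlation. Of 40 glutathione S-transferases 13 rose and 6 fell (adjusted p = 0.0029, or adjusted p = 0.29 with an estimated correlation). Of 77 NAC factors 20 rose and 14 fell (21 and 15 adjusted over the list alone; adjusted p = 0.019, or adjusted p = 0.291 with an estimated correlation). The NAC median was 0.02, and -0.0015 with slide as a block. The set test did not pass for the 83 MYB factors, 18 up and 23 down (adjusted p = 0.21; 19 and 25 adjusted over the list alone), or the 166 cytochromes P450, 16 up and 52 down (0.205; 16 and 54). Nor did it pass for the 57 UDP-glycosyltransferases, 9 up and 16 down (0.841; 10 and 18), the 50 expansins and xyloglucan endotransglucosylases, 9 up and 17 down (0.537; 10 and 17), or the 57 SAUR genes, 9 up and 20 down (0.742; 9 and 22).

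Of 130 genes named here and past the threshold at 1 h, 20 of them picked for it, 125 changed the same way in all 5 experiments. The count at 1 h was 4407 with slide as a block and 5521 with scan date as a block. Within the scan dates alone 2592 genes were called on the first (3 samples per group) and 3278 on the second (2 samples per group), and 100% of the 5302 genes had the same sign on each. On the slides that held 1 sample of each group, 97.2% and 99.3% of them did. Genes and lists past the threshold were called with these same samples, so here and below a kept sign is largely built in. Over all genes the changes within the 2 scan dates had r = 0.988 and 0.977 with the reported ones. With slide as a block 20 of the 21 lists past the threshold stayed past it, with scan date as a block 21 did, and the median of all 21 kept its sign within each scan date. Some random splits of the same samples put as many lists past the threshold at the preset correlation. With the normexp background correction 1615 genes were called.

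**Figure D1:**
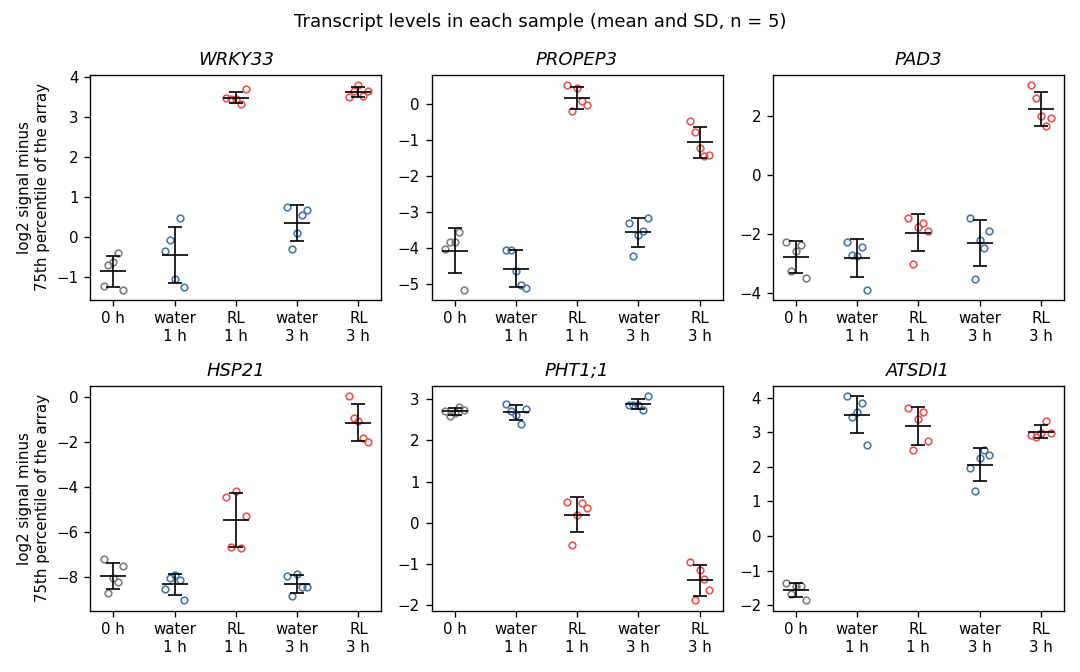
Level of 6 transcripts in each sample, as log2 signal minus the array's 75th percentile, by group (open circles, samples; dash and bars, mean and SD, n = 5). WRKY33 and PROPEP3 lie higher with RL at both times, PAD3 and HSP21 mostly at 3 h, PHT1;1 lies lower with RL, and ATSDI1 lies 5.07 higher in water at 1 h than at 0 h.

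**Figure D2:**
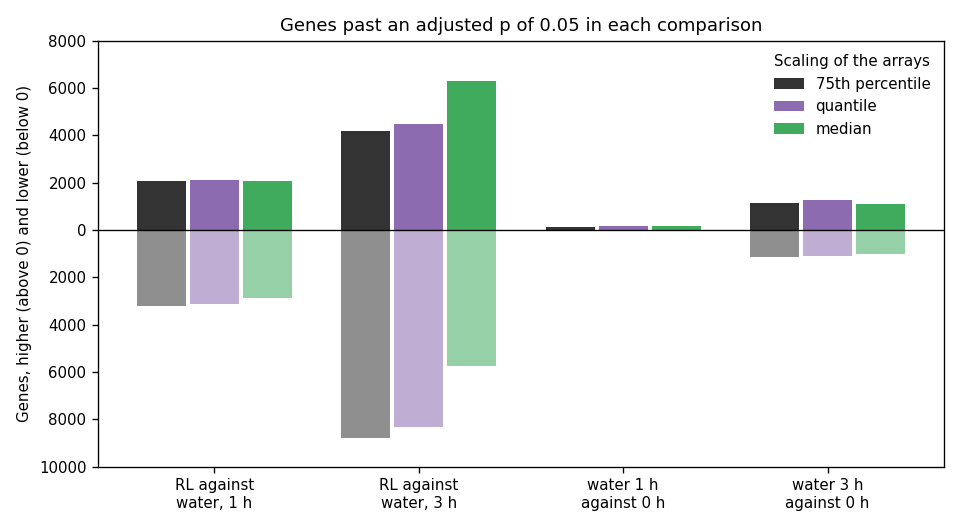
Number of genes past an adjusted p of 0.05 in each comparison, higher above 0 and lower below 0, with the arrays scaled to their 75th percentile, by quantiles or to their median. At 3 h of RL 8781 genes were lower with the 75th percentile and 5732 with the median.

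What RL had changed by 3 h was asked by setting the RL 3 h samples against the water 3 h samples. All 13 measured heat shock genes and all 25 detoxification genes rose, and all 14 root markers fell. The transporter ABCG40 rose 190-fold, at 7.57 ± 0.231 (adjusted p = 5.87e-17), and PAD3, which had not passed at 1 h, rose by 4.57 ± 0.382 (adjusted p = 4.25e-10). PHT1;1 stood at -4.27. In total 12968 genes differed, 4187 higher and 8781 lower with RL. By at least 2-fold 1690 rose and 2183 fell. With the median of each array as the scaling point 12022 differed, 6290 higher and 5732 lower, and the median change of all genes moved from -0.155 to 0.0312.

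The largest rises at 3 h included AT5G57510, at least 83.9-fold, AT1G22810, at least 87.5-fold, the small heat shock proteins HSP21, at least 40.6-fold, and HSP17.6A (AT5G12030), 94.7-fold, and NHL25 (AT5G36970), at least 33.6-fold. AT4G37710 rose at least 48.7-fold, GSTU12 97.3-fold, the kinase MAPKKK19 (AT5G67080) by 6.53 ± 0.224 and AT4G37290 at least 71.9-fold. The largest falls exceeded those at 1 h. The peroxidase AT1G05240 fell at least 147-fold, to below background in all RL samples (adjusted p = 1.44e-14). AGP3 fell at least 129-fold, and the peroxidases AT3G01190 and AT5G17820 at least 171-fold and 168-fold. AT4G12545, a lipid transfer protein, fell at least 89.5-fold and the acyltransferase AT4G15390 at least 94.2-fold. The peroxidase AT1G30870 fell at least 66.5-fold, BGLU35 at least 50.7-fold and the lectin AT1G52060 at least 42.4-fold. The extensin AT1G26250 fell at least 117-fold with its brightest probe, and the lowest change among its other kept probes was -1.88.

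In the rapid immune response at 3 h 25 of 26 rose, with ERF6 at 4.17, YLS9 (AT2G35980) at 4.70, ATL6 at 2.17 and PUB24 at 3.09, and a median of 2.71, and adjusted p = 2.92e-15, or adjusted p = 0.113 with an estimated correlation. FRK1 stood at 0.63 ± 0.572 (adjusted p = 0.348), and in water it was itself 1.59 higher at 3 h than at 0 h without passing (adjusted p = 0.0719). WRKY33 rose by 3.28 ± 0.253 and PROPEP3 by 2.51 ± 0.282. Among the receptors and signalling genes 25 of 31 rose, with PEPR2 at 2.55, PEPR1 (AT1G73080) at 1.83 and the co-receptor BAK1 (AT4G33430) at 0.88, against falls of LYM1 (AT1G21880) and LYM3 (AT1G77630), named after their values of -0.43 and -0.47 were seen (adjusted p = 4.76e-12, or adjusted p = 0.144 with an estimated correlation). RBOHD rose by 2.02 ± 0.206 and MPK3 by 1.36 ± 0.12, and SD1-29, outside the list as tested, by 1.04 ± 0.174. In the touch and calcium binding list 9 of 10 rose, with CML37 at 6.08 and TCH4 at 3.40, and CAX3 (AT3G51860), a vacuolar calcium exchanger named after its value was seen, changed by -1.52 (adjusted p = 6.29e-06, or adjusted p = 0.209 with an estimated correlation).

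In the jasmonate pathway at 3 h 20 of 30 rose and 4 fell (20 and 5 adjusted over the list alone), with OPR3 (AT2G06050) at 1.92, AOC3 at 3.49, JAZ10 (AT5G13220) at 2.67 and MYC2 at 1.59. The set test gave adjusted p = 2.74e-08, or adjusted p = 0.209 with an estimated correlation. In the ethylene pathway 21 of 29 rose and 4 fell, with ERF-1 at 3.27, ERF1 (AT3G23240) at 4.59 and ERF11 (AT1G28370) at 2.96, and adjusted p = 8.88e-08, or adjusted p = 0.135 with an estimated correlation. In the salicylic acid pathway 11 of 24 rose and 4 fell, with NPR3 at 2.24 and NPR4 (AT4G19660) at 0.82. The list as a whole had adjusted p = 0.00629, or adjusted p = 0.519 with an estimated correlation. EDS16 stood at -0.22 ± 0.247 (adjusted p = 0.442) and PDF1.2 at 0.50 ± 0.25 (adjusted p = 0.0844). In the abscisic acid and water stress list 9 of 23 rose and 5 fell, with the phosphatases ABI2 at 1.67, HAB1 (AT1G72770) at 0.89 and HAI1 (AT5G59220) at 1.77 among the rises, and adjusted p = 0.0319, or adjusted p = 0.291 with an estimated correlation. The auxin list did not pass, with 7 of 17 up and 6 down (adjusted p = 0.0829), although GH3.3 (AT2G23170), an auxin-conjugating enzyme, rose by 3.74, SAUR9 by 3.61 and IAA2 by 1.79. The falls in these lists, named after their values were seen, were JMT (AT1G19640) at -0.97, COI1 at -0.39, JAR1 at -0.35 and LOX6 (AT1G67560) at -0.28 for jasmonate. For ethylene they were the chitinase HCHIB (AT3G12500) at -2.85, AT2G19590 at -1.79, PR4 (AT3G04720) at -1.67 and EIN2 at -0.42. For salicylic acid they were AT4G10500 at -2.53, FMO1 (AT1G19250) at -2.19, EPS1 (AT5G67160), which the naming rule covers, at -1.49 and WRKY54 (AT2G40750) at -0.98. For abscisic acid and water stress they were DREB1A (AT4G25480) at -2.32, LTI78 (AT5G52310) at -0.77, COR15A (AT2G42540) at -0.47, AT5G66400 at -0.45 and P5CS1 (AT2G39800) at -0.41.

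In the xenobiotic detoxification list at 3 h 25 of 25 rose, with GSTU4 (AT2G29460) at 4.97 and GSTU11 at 4.99, a median of 1.99 and adjusted p = 7.46e-15, or adjusted p = 0.0542 with an estimated correlation. In the heat shock list 13 of 13 rose, with HSFB2A at 3.3 and Hsp70b (AT1G16030) at 3.77, a median of 3.14 and adjusted p = 8.19e-10, or adjusted p = 0.113 with an estimated correlation. In the tryptophan, camalexin and indole glucosinolate list 24 of 26 rose (25 adjusted over the list alone) and MYB34 fell by 2.63 on the log2 scale, with the synthesis enzymes TSB1 (AT5G54810) at 1.06 and ASA1 (AT5G05730) at 1.95, CYP81F2 at 3.75 and a median of 1.68. Its set test gave adjusted p = 1.04e-11, or adjusted p = 0.135 with an estimated correlation. In the mitochondrial stress list AOX1D rose by 6.16, BCS1 by 2.95, NDB2 (AT4G05020) by 2.05, AOX1A by 1.36 and NAC13, named after its value was seen, by 0.69, which is 5 of 6 members (adjusted p = 0.00114, or adjusted p = 0.194 with an estimated correlation). Of 5 sugar starvation genes DIN2, ASN1, AT4G35770 and DIN10 (AT5G20250) rose by 4.59, 3.70, 3.43 and 0.86, and GBF6 (AT4G34590), named after its value of -0.49 was seen, fell (adjusted p = 0.0201, or adjusted p = 0.135 with an estimated correlation). Among the 14 sphingolipid genes the inositolphosphorylceramide synthase AtIPCS2 rose by 1.71 and the ceramide synthase LOH2 by 1.85, while LAG1 (AT3G25540), another ceramide synthase, changed by -1.05. In that list 5 rose and 3 fell, or 8 and 1 with median scaling (adjusted p = 0.0496, or adjusted p = 0.189 with an estimated correlation, 0.0584 with slide, 0.0544 with scan date and 0.0601 with the experiment as a block). The others, all but SBH1 named after their values were seen, were LCB1 (AT4G36480) at 0.49, SBH1 (AT1G69640) at 0.45, ACD5 (AT5G51290) at 0.34, SBH2 (AT1G14290) at -0.26 and LCB2 (AT5G23670) at -0.18.

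All 14 root markers fell at 3 h, with SHV2 at least 26.1-fold lower, PHT1;1 at -4.27 and CASP1 at -2.88, a median of -2.72 and adjusted p = 8.79e-07, or adjusted p = 0.135 with an estimated correlation. The dimmer RL 3 h arrays moved with this group, and with quantile normalization the median of the markers was -2.55. In the flavonoid and anthocyanin list 11 of 12 fell, with MYB12 (AT2G47460) at -3.69, MYB111 at -2.95, TT4 (AT5G13930), chalcone synthase, at -1.83 and FLS1 (AT5G08640) at -1.81. The set test gave adjusted p = 0.00064, or adjusted p = 0.29 with an estimated correlation. In the aliphatic glucosinolate list 14 of 15 fell (14 down and 1 up adjusted over the list alone), with MYB28 at -2.52, GSTF11 at -2.21, IPMI1 at -1.98 and BCAT4 (AT3G19710) at -1.40, and adjusted p = 0.000845, or adjusted p = 0.291 with an estimated correlation. In the sterol synthesis list 12 of 14 fell, or 7 with median scaling, and 1 rose (12 and 2 adjusted over the list alone), with the reductase FK (AT3G52940) at -0.68 and SMT3 at -0.68, and HMG1 (AT1G76490), named after its value was seen, rose by 0.18 (adjusted p = 0.0391, or adjusted p = 0.442 with an estimated correlation). Of 15 cell cycle genes 10 fell and 0 rose without the list passing (adjusted p = 0.0546), among them CYCD3;1 at -0.75 and MCM2 (AT1G44900) at -0.60, and with slide or the experiment as a block it did (adjusted p = 0.0415 and 0.0314).

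Photosynthesis (shoot) genes changed little and in a direction that depended on the scaling. Of 33 genes 18 rose and 3 fell with the 75th percentile (median 0.25, adjusted p = 0.00173, or adjusted p = 0.62 with an estimated correlation). With quantile normalization 1 rose and 3 fell (median -0.01), 0 rose and 3 fell in the deposited values of the authors (median 0.0041), and 26 rose and 1 fell with median scaling. Set against the median of all genes, the list stood at 0.40, 0.12, 0.09 and 0.40 in these scalings. GAPA (AT3G26650) stood at 0.24 and PSAK (AT1G30380) at 0.33 with the 75th percentile, and the falls were PORB (AT4G27440) at -0.51, POR C (AT1G03630) at -0.31 and HEMA1 (AT1G58290) at -0.22, POR C being chosen after its value was seen. In 12 iron genes 4 rose and 5 fell (adjusted p = 0.841), or 5 and 4 with median scaling. The regulators BTS (AT3G18290), PYE, bHLH38 (AT3G56970) and BHLH101 (AT5G04150) rose by 1.26, 0.56, 1.12 and 2.27, while FRO2 fell at least 9.58-fold. IRT1 fell at least 8.37-fold, and FER1 (AT5G01600), NAS4 (AT1G56430) and FER3 (AT3G56090) stood at -0.72, -0.55 and -0.49, of which only BTS, FRO2, IRT1 and FER3 fall under the naming rule. Of 22 clock genes 3 rose and 5 fell (adjusted p = 0.255; 3 and 4 adjusted over the list alone), or 8 and 2 with median scaling. The rises were BOA, TOC1 (AT5G61380) and PCL1 (AT3G46640) at 1.42, 0.53 and 0.50, and the falls AT1G18330 at -0.85, PRR9 (AT2G46790) at -0.59, ELF4 at -0.56, PRR3 at -0.46 and GI (AT1G22770) at -0.33, the last chosen after its value was seen, as were PRR9, ELF4 and PRR3. Of 19 phenylpropanoid and lignin genes 7 rose and 5 fell (adjusted p = 0.152), or 6 and 7 in the deposited values of the authors, and AT3G13610, 4CL3 (AT1G65060), AT4G36220, PAL3 (AT5G04230) and ATCAD4 stood at -3.80, -1.41, -0.73, -0.65 and -0.54. Of 14 unfolded protein response genes BZIP60 and BIP3 (AT1G09080) rose by 1.75 and 1.4 and 9 fell (10 adjusted over the list alone; adjusted p = 0.72). Of 12 low oxygen genes ERF71 and AT4G33070 rose by 2.60 and 1.41, and AT5G39890, AT3G10040, FTM1 (AT1G43800) and ERF73 (AT1G72360) stood at -1.53, -1.32, -1.0 and -0.87 (adjusted p = 0.781). Among 8 reference genes UBQ10 (AT4G05320) rose by 0.59 and TUB2 (AT5G62690) changed by -0.27 (adjusted p = 0.452). BIP3, AT5G39890 and FTM1 were chosen after their values were seen, as were PAL3 and ATCAD4.

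Of 25 ERF factors 20 rose at 3 h and ERF73 alone fell, with TDR1 at 4.66 (adjusted p = 2.04e-09, or adjusted p = 0.0929 with an estimated correlation). Of 20 U-box ligases 13 rose and 4 fell, with PUB23 at 3.18 and SAUL1 (AT1G20780) at 1.39 (adjusted p = 2.5e-05, or adjusted p = 0.19 with an estimated correlation). The falls were PUB18 (AT1G10560), PUB29 (AT3G18710), PUB8 and PUB26 (AT1G49780) at -0.60, -0.57, -0.49 and -0.29, chosen after their values were seen. Of 40 glutathione S-transferases 24 rose and 10 fell, with GSTF8 (AT2G47730) at 2.05 and GSTU14 (AT1G27140) at least 10.3-fold lower (adjusted p = 0.000132, or adjusted p = 0.183 with an estimated correlation). Of 57 UDP-glycosyltransferases 28 rose and 19 fell (29 and 19 adjusted over the list alone), with UGT85A1 (AT1G22400) at 2.13 and UGT71C1 (AT2G29750) at -3.91 (adjusted p = 0.00502, or adjusted p = 0.194 with an estimated correlation). Of 60 WRKY factors 26 rose and 20 fell (27 and 22 adjusted over the list alone), with WRKY28 (AT4G18170) at 2.87 and WRKY53 at 0.64 (adjusted p = 0.00625, or adjusted p = 0.51 with an estimated correlation). Of 77 NAC factors 28 rose and 21 fell, with NAC062 (AT3G49530) at 2.07 and NAC070 (AT4G10350), a root cap factor, at least 4.65-fold lower (adjusted p = 0.0269, or adjusted p = 0.314 with an estimated correlation), and their median of 0.05 was -0.11 on the second scan date. Of 28 genes with the symbol CRK 15 rose and 10 fell (adjusted p = 0.0198, or adjusted p = 0.582 with an estimated correlation), or 15 and 8 of 26 without the CDPK-related kinases (adjusted p = 0.00643, or adjusted p = 0.526 with an estimated correlation). Of 10 wall-associated kinases 6 rose while WAKL1, WAKL5 (AT1G16160) and WAK2 (AT1G21270) stood at -1.38, -1.23 and -1.05, chosen after their values were seen (adjusted p = 0.0319, or adjusted p = 0.379 with an estimated correlation). Of 50 expansins and xyloglucan endotransglucosylases 10 rose and 34 fell (10 and 36 adjusted over the list alone), with XTH14 at least 97.2-fold lower and EXPB3 (AT4G28250) at -2.10 (adjusted p = 0.0202, or adjusted p = 0.398 with an estimated correlation). Of 57 SAUR genes 12 rose and 39 fell, with AT4G31320 at least 19.3-fold lower and AT5G20820 at -3.25 (adjusted p = 0.0252, or adjusted p = 0.356 with an estimated correlation). The 83 MYB factors, 21 up and 40 down (adjusted p = 0.616), and the 166 cytochromes P450, 40 up and 94 down (0.113; 40 and 95 adjusted over the list alone), did not pass.

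Of 171 genes named here and past the threshold at 3 h, 20 of them picked for it, 158 changed the same way in all 5 experiments. The count at 3 h was 12789 with slide as a block and 13147 with scan date as a block. Within the scan dates alone 10145 genes were called on the first and 10866 on the second, where 100% and 99.9% of the 12968 genes had the same sign, as did 99.2%, 99.0% and 99.2% on the slides with 1 sample of each group. That sign is largely built in, as the genes were called with these samples. Over all genes r with the reported changes was 0.994 and 0.988 on the scan dates. With slide or scan date as a block 27 of the 28 lists stayed past the threshold, and the median of 28 kept its sign on the first scan date and of 27 on the second. The normexp background correction called 5934 genes. With an estimated correlation 0 of the 28 list calls at 3 h were kept by camera, with 14 of 38 lists past an unadjusted p of 0.05.

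**Figure D3:**
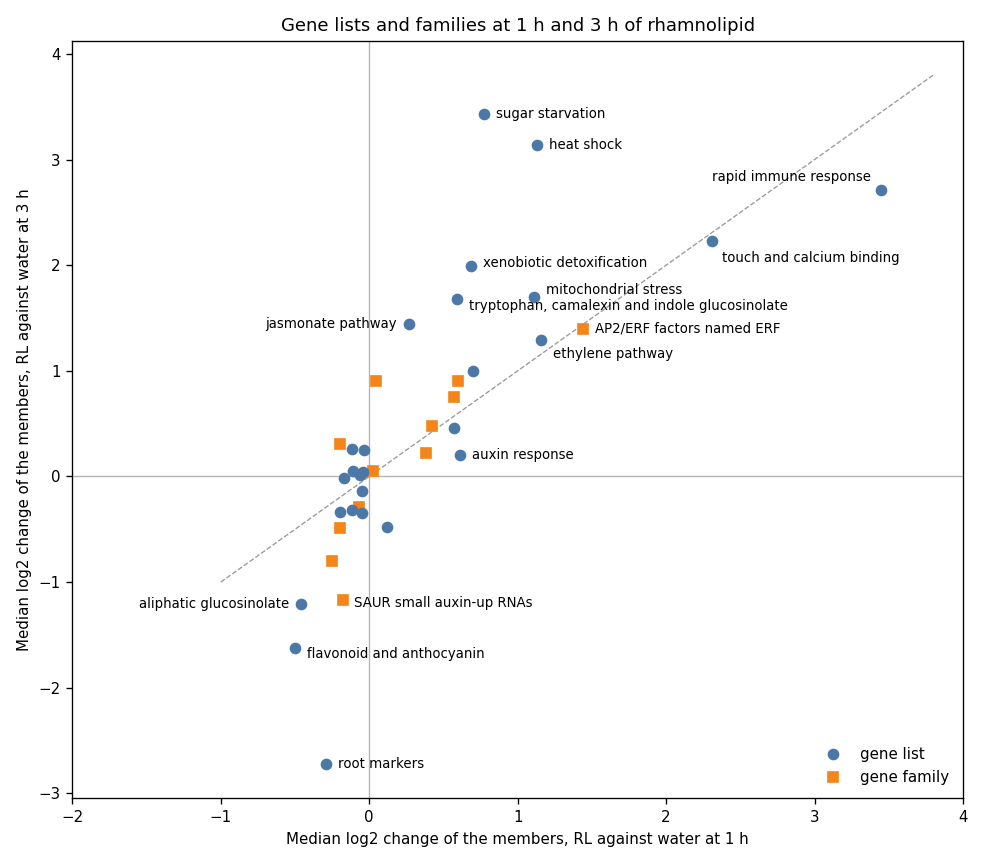
Median log2 change of the members of 38 gene lists and families with RL against water, at 1 h (horizontal axis) and 3 h (vertical axis), with the dashed line marking equal changes. Rapid immune genes lie at 3.45 and 2.71, heat shock genes at 1.13 and 3.14 and root markers at -0.29 and -2.72, while the photosynthesis list at 3 h, at 0.25, lies at -0.01 with quantile normalization.

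**Figure D4:**
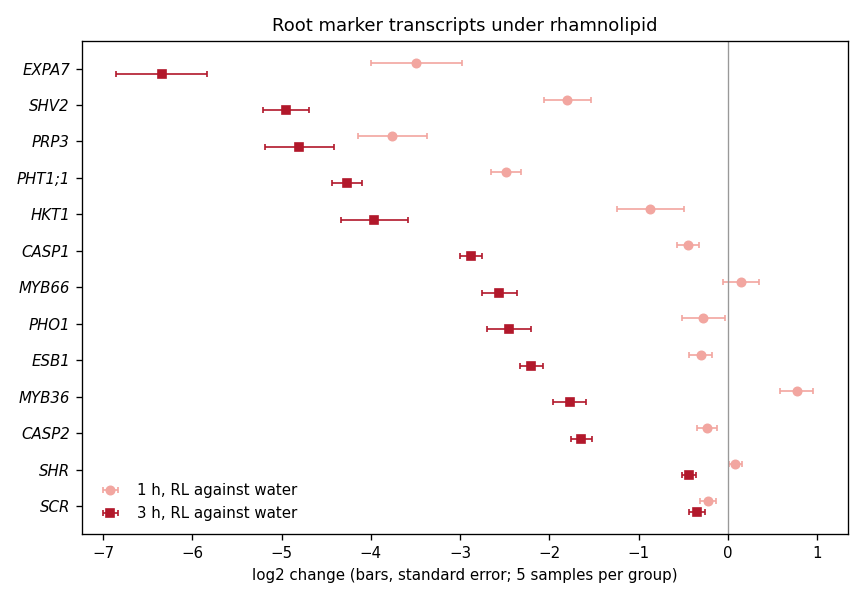
Log2 change of root marker transcripts with RL against water at 1 h (circles) and 3 h (squares), with bars for the SE (5 samples per group). At 3 h those shown lie from -0.34 to -6.34, and the background limits SHV2 and may limit EXPA7 and PRP3.

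Whether the RL response differed between 3 h and 1 h was tested as the difference between the 2 RL effects, and 7672 genes differed, 2701 with a higher and 4971 with a lower effect at 3 h, 683 and 1460 of them by at least 2-fold. The effect on PAD3 was 3.71 ± 0.54 higher at 3 h (adjusted p = 1.09e-05), and CYP71A13 (AT2G30770), another camalexin enzyme, was well above background on the RL 3 h arrays and on no array of the other groups, so no size is given for it. Effects on the early immune genes PROPEP3, WRKY53 and MPK3 were lower at 3 h, at -2.25 ± 0.399 (adjusted p = 0.000108), -1.27 ± 0.354 (adjusted p = 0.00658) and -1.11 ± 0.169 (adjusted p = 2.01e-05). For WRKY33, RBOHD and SD1-29 the differences of -0.66 ± 0.358, -0.39 ± 0.291 and 0.42 ± 0.246 did not pass (adjusted p = 0.154, 0.312 and 0.184). With median scaling 7647 genes differed, but 4708 were then higher and 2939 lower, as the median of all genes moved from -0.0876 to 0.0937.

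By the values measured, the largest higher effects at 3 h were those on the small heat shock proteins ATHSP22.0 (AT4G10250), 5.45 ± 0.782, and AT1G52560, 4.96 ± 0.512, on the glycosyltransferase UGT76E12 (AT3G46660), 4.96 ± 0.533, and on ELI3-2 (AT4G37990), an alcohol dehydrogenase of the phenylpropanoid list, 4.74 ± 0.816. The largest lower effects were those on the protease inhibitor AT3G04320, -6.23 ± 1.06, AT4G15390, -6.22 ± 0.808, the peroxidases AT5G24070, -6.07 ± 0.669, and AT3G01190, -5.90 ± 0.561, and the lectin AT1G52070, -5.63 ± 0.76. Their adjusted p ran from 5.02e-08 to 8.13e-05. The 5 genes with a lower effect were well above background on 1 of 5 RL 3 h arrays, and ATHSP22.0 and AT1G52560 on 0 of 5 water 3 h arrays, so the sizes and their order are limited by the background.

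By lists, the RL effect was higher at 3 h for heat shock genes, 11 of 13 higher and 0 lower (12 and 0 adjusted over the list alone), with Hsp70b at 3.64 (adjusted p = 2.74e-08, or adjusted p = 0.135 with an estimated correlation), and for xenobiotic detoxification, 20 of 25 higher, with ABCG40 at 4.25 (adjusted p = 1.67e-10, or adjusted p = 0.0964 with an estimated correlation). It was also higher for the jasmonate pathway, 11 of 30 higher and 2 lower (12 and 2 adjusted over the list alone), with OPR3 at 1.27 (adjusted p = 5.8e-05, or adjusted p = 0.316 with an estimated correlation), and for the tryptophan, camalexin and indole glucosinolate list, 14 of 26 higher and 2 lower (15 and 3 adjusted over the list alone), with ASA1 at 1.48 (adjusted p = 3.32e-05, or adjusted p = 0.291 with an estimated correlation). For UDP-glycosyltransferases 27 of 57 were higher and 10 lower (27 and 12 adjusted over the list alone; adjusted p = 0.000277, or adjusted p = 0.122 with an estimated correlation), and for glutathione S-transferases 17 of 40 and 9 (adjusted p = 0.00575, or adjusted p = 0.291 with an estimated correlation). Higher effects also outnumbered lower ones for sphingolipid genes, 5 of 14 and 1 (adjusted p = 0.0309, or adjusted p = 0.144 with an estimated correlation), for sugar starvation, 3 of 5 and 0 (4 and 0 adjusted over the list alone; adjusted p = 0.0252, or adjusted p = 0.135 with an estimated correlation), and for the clock, 1 of 22 and 0, or 8 and 0 with median scaling (adjusted p = 0.0252, or adjusted p = 0.312 with an estimated correlation). LOH2 and DIN2 stood at 1.33 and 3.21, and PCL1 at 0.72. The effect was lower at 3 h for 12 of 14 root markers, with MYB36 at -2.54 (adjusted p = 1.4e-08, or adjusted p = 0.104 with an estimated correlation), for 9 of 12 flavonoid genes, or 5 in the deposited values of the authors, with MYB12 at -2.88 (adjusted p = 0.00157, or adjusted p = 0.311 with an estimated correlation), and for 10 of 15 aliphatic glucosinolate genes, 1 being higher (adjusted p = 0.00726, or adjusted p = 0.398 with an estimated correlation). The same held for 10 of 15 cell cycle genes, or 6 with quantile normalization and 2 with median scaling, with MCM2 at -0.53 (adjusted p = 0.0201, or adjusted p = 0.556 with an estimated correlation). It was lower too for 30 of 50 expansins and xyloglucan endotransglucosylases with 3 higher (adjusted p = 0.00269, or adjusted p = 0.29 with an estimated correlation), and 31 of 57 SAUR genes with 6 higher, or 16 and 7 in the deposited values of the authors (32 and 6 adjusted over the list alone; adjusted p = 0.00629, or adjusted p = 0.29 with an estimated correlation). Among families of enzymes and factors it was lower for 32 of 83 MYB factors with 7 higher (33 and 9 adjusted over the list alone; adjusted p = 0.0186, or adjusted p = 0.267 with an estimated correlation), and 70 of 166 cytochromes P450 with 23 higher (71 and 25 adjusted over the list alone; adjusted p = 0.0334, or adjusted p = 0.519 with an estimated correlation). The photosynthesis (shoot) list passed with 3 of 33 higher (0 adjusted over the list alone; median 0.29, adjusted p = 0.00064, or adjusted p = 0.58 with an estimated correlation), but its median was -0.04 with quantile normalization, and 24 were higher with median scaling. The rapid immune list did not pass, with 2 of 26 higher and 9 lower (2 and 11 adjusted over the list alone; adjusted p = 0.275).

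The interaction count was 7699 with slide as a block and 7893 with scan date as a block, and 3748 and 4854 genes were called within the scan dates alone, where the medians of all 18 lists past the threshold kept their sign. With either block all 18 stayed past it. The calls at 1 h and 3 h shared 1747 genes that rose and 2606 that fell at both times, where independent lists would share 434.9 and 1423, and 252 genes were called in opposite directions. Across genes, which are not independent replicates, the changes at the 2 times had r = 0.756 and rho = 0.590.

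What handling, carrier and time changed without RL was asked by setting the water samples against the 0 h samples. After 1 h in water 177 genes differed, 126 higher and 51 lower, and 38 of the rises and 0 of the falls reached 2-fold. Genes that plants switch on when sulfur is short were among the largest rises. ATSDI1 (AT5G48850), a marker of sulfur deficiency, rose 33.5-fold (5.07 ± 0.253, adjusted p = 2e-11), BGLU28 (AT2G44460), a glucosidase of the same response, by 4.43 ± 0.337, and LSU3 (AT3G49570) and LSU1 (AT3G49580) by 3.77 ± 0.226 and 3.54 ± 0.284. AT1G12030 rose by 4.43 ± 0.351. The falls were small, with the nitrate reductase NIA1 (AT1G77760) at -0.95 ± 0.223, HB52 (AT5G53980) at -0.84 ± 0.152, AT1G63820 at -0.76 ± 0.166 and the potassium channel SKOR (AT3G02850) at -0.74 ± 0.112, and AT1G19320 was called while its probe was below background on all arrays of both groups. With the experiment number as a block 279 genes differed as a fixed term and 275 as a random one. With slide as a block 93 did and with scan date as a block 187, while 37 and 18 were called within the scan dates alone, and 100% of the 177 genes had the same sign on both. Without 0 h replicate 4 the count was 115 and without water 1 h replicate 1 it was 109.

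Few members of the fixed lists passed in water at 1 h, and with an estimated correlation none of the 14 list calls was kept, the smallest such adjusted p being 0.135. The calls rested on small shifts. In the jasmonate list AOS (AT5G42650), AOC1 (AT3G25760) and AOC2 (AT3G25770), early enzymes of jasmonate synthesis, rose by 0.76, 0.78 and 0.63 (3 of 30; median 0.22, adjusted p = 6.45e-12). In the rapid immune list PHI-1 (AT1G35140) rose by 1.3 (1 of 26, 4 adjusted over the list alone; adjusted p = 2.21e-06), in the touch list TCH4 rose by 0.98 (1 of 10; adjusted p = 0.000277), and in the low oxygen list AT5G15120 rose by 2.03 (1 of 12, 3 adjusted over the list alone; adjusted p = 0.00383, and 0.317 with slide as a block). With slide as a block 9 of the 14 lists stayed past the threshold and with scan date as a block 13, and the medians of 14 kept their sign on the first scan date and of 10 on the second.

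After 3 h in water 2278 genes differed from 0 h, 1127 higher and 1151 lower, and 274 of the rises and 8 of the falls reached 2-fold. In the mitochondrial stress list rises were seen, with AOX1A at 3.32, NAC13 at 2.95, BCS1 at 2.42 and AOX1D at 1.12 (4 of 6, 5 adjusted over the list alone; adjusted p = 1.26e-08, or adjusted p = 0.0568 with an estimated correlation). Among the largest rises were those of AT4G12735, 6.40 ± 0.405, BGLU28, 6.26 ± 0.337, the low oxygen factor ERF71, at least 29.5-fold, AT5G55150, at least 11.2-fold, and the ATPase AT2G18193, 5.11 ± 0.32. Among the largest falls were those of HEC2 (AT3G50330), at least 2.14-fold, MYB29 (AT5G07690), a regulator of aliphatic glucosinolates, -1.48 ± 0.392, AT2G22200, -1.43 ± 0.269, ESE3 (AT5G25190), -1.15 ± 0.186, and MAKR6 (AT5G52900), -1.14 ± 0.207.

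Of 57 UDP-glycosyltransferases 13 rose in water by 3 h (16 adjusted over the list alone), with UGT73C6 (AT2G36790) at 4.1, and the call was the only one of 25 kept with an estimated correlation (adjusted p = 3.65e-09, and adjusted p = 0.0262 with an estimated correlation). In the xenobiotic list 9 of 25 rose (11 adjusted over the list alone), with CYP81D8 at 3.47 and UGT74E2 (AT1G05680) at 2.84 (adjusted p = 1.94e-10, or adjusted p = 0.0964 with an estimated correlation). In the rapid immune list 12 of 26 rose (17 adjusted over the list alone), with MPK11 (AT1G01560) at 1.83 and RHL41 (AT5G59820) at 1.65 (adjusted p = 1.11e-12, or adjusted p = 0.135 with an estimated correlation), and WRKY33 and EDS16 of the fixed panel rose by 1.21 and 1.14. In the jasmonate list 9 of 30 rose (21 adjusted over the list alone), with AOS at 1.15 (adjusted p = 1.15e-10, or adjusted p = 0.144 with an estimated correlation), and in the low oxygen list HB1 (AT2G16060), LBD41 (AT3G02550), AT5G15120 and ERF71 rose (4 of 12, 5 adjusted over the list alone; adjusted p = 8.32e-06, or adjusted p = 0.29 with an estimated correlation). Of 15 cell cycle genes 9 fell (15 adjusted over the list alone), with CYCB1;1 (AT4G37490) at -0.52 (adjusted p = 4.84e-08, or adjusted p = 0.194 with an estimated correlation). Of 15 aliphatic glucosinolate genes 8 fell (10 adjusted over the list alone), with MYB28 at -0.74 (adjusted p = 1.47e-05, or adjusted p = 0.209 with an estimated correlation). Of 14 unfolded protein response genes 8 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 0.0025, or adjusted p = 0.398 with an estimated correlation). Of the 14 root markers 1 fell, SHR (AT4G37650) at -0.29 (list adjusted p = 0.472).

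Without 0 h replicate 5, water 3 h replicate 1 or water 3 h replicate 5 the count at 3 h in water was 1471, 1324 or 1283. It was 1924 with slide as a block and 2499 with scan date as a block. Within the scan dates alone, with 3 and 2 samples per group, it was 169 and 185, and 100% of the 2278 genes kept their sign, as did 96.0% to 99.6% on single slides. With either block all 25 lists stayed past the threshold, and their medians kept their sign within both scan dates.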

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

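The divisions of the experiment pairs between the times, the spread of the root markers, the comparison of root hair with inner root genes, the sulfur list within scan dates and the share of falls with median scaling were tests chosen after the results were seen.

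For the genes named, 743 combinations of a gene and a group were searched for a sample apart from the other 4, by its gap to the nearest sample over the range of the group with a critical value of 0.71. In 46, or 6.19%, a sample stood apart, where chance gives about 1 in 20. RL 3 h replicate 1 held 13 of these, more than any other sample. It was highest for NAC13 (0.817), AT1G52070 (0.775), COR15A (0.727), AT3G04320 (0.77), AT4G12545 (0.774), AT4G33070 (0.746), AGP3 (0.796), AT5G24070 (0.826) and EPS1 (0.782), and lowest for GSTF11 (0.894), BTS (0.751), AT4G35770 (0.751) and TOC1 (0.71). For the root genes AT3G04320, AT1G52070, AGP3 and AT5G24070 it lay at -2.30, -4.13, -5.67 and -4.89 against means of -8.20, -8.15, -8.52 and -8.40 in the other 4 samples. The other RL 3 h samples apart were replicate 3 for IAA2 (0.761) and replicate 5 for SBH1 (0.884).

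Among the RL 1 h samples replicate 2 was lowest for AT3G13610 (0.793), PAD3 (0.719), CRK27 (0.83), ELI3-2 (0.719) and AT5G57510 (0.719). Replicate 4 was highest for CRT1b (0.77) and COI1 (0.732) and lowest for ABF3 (0.82), replicate 1 lowest for ATERDJ3B (0.761) and highest for CRK31 (0.83), replicate 3 lowest for UGT76E12 (0.717) and replicate 5 highest for ATL6 (0.775). Among the water 1 h samples replicate 4 was highest for SMT3 (0.721) and EIN2 (0.78) and lowest for AT3G01190 (0.788), IAA2 (0.759), MYB111 (0.836) and MYB36 (0.755). Replicate 1 was highest for AT1G14550 (0.776) and replicate 5 for AT4G37710 (0.916). Among the water 3 h samples replicate 2 was lowest for PUB26 (0.716), GSTU11 (0.712), IPMI1 (0.825), MAKR6 (0.754) and RHL41 (0.742), replicate 1 highest for OPR3 (0.73) and lowest for FER3 (0.937), replicate 4 highest for MCM2 (0.722) and replicate 5 highest for IAA2 (0.866). At 0 h replicate 5 was lowest for MPK11 (0.712) and highest for UGT73C6 (0.715). Of 30 combinations of an array measure and a group, 1 had an array apart, the 75th percentile of water 3 h replicate 1, which was lowest (0.753).

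The RL response differed between 3 h and 1 h for 7672 genes. Of the genes named in the report for this difference, the effect was higher at 3 h on ABCG40 (4.25), Hsp70b (3.64), AT1G52560 (4.96), OPR3 (1.27), LOH2 (1.33), PAD3 (3.71), PCL1 (0.72), UGT76E12 (4.96), DIN2 (3.21), ATHSP22.0 (5.45), ELI3-2 (4.74) and ASA1 (1.48), and on CYP71A13 (adjusted p = 2.72e-07), for which no size is given, since it was well above background on 5 RL 3 h arrays alone. It was lower on MCM2 (-0.53), AT1G52070 (-5.63), MYB12 (-2.88), AT3G01190 (-5.90), AT3G04320 (-6.23), MPK3 (-1.11), AT4G15390 (-6.22), WRKY53 (-1.27), AT5G24070 (-6.07), MYB36 (-2.54) and PROPEP3 (-2.25). The background also limits the values of ATHSP22.0 and AT1G52560, on 0 of 5 water 3 h arrays, and of AT1G52070, AT3G01190, AT3G04320, AT4G15390 and AT5G24070, on 1 of 5 RL 3 h arrays. Lists with a higher effect by the set test were the jasmonate pathway (adjusted p = 5.8e-05), tryptophan and camalexin (3.32e-05), xenobiotic detoxification (1.67e-10), heat shock (2.74e-08), photosynthesis in the shoot (0.00064), clock (0.0252), sphingolipid (0.0309), sugar starvation (0.0252), glutathione S-transferases (0.00575) and UDP-glycosyltransferases (0.000277). Those with a lower effect were aliphatic glucosinolate (0.00726), flavonoid (0.00157), root markers (1.4e-08), cell cycle (0.0201), MYB (0.0186), cytochromes P450 (0.0334), expansins (0.00269) and SAUR (0.00629). With an estimated correlation 0 of these 18 list differences were kept by camera, with 6 of 38 past an unadjusted p of 0.05.

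Of 4087 kept probes that matched no locus and entered no comparison above, 571 differed with RL at 1 h and 1838 at 3 h, against 4 in water at 1 h and 103 in water at 3 h.

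Of 100 splits of the same samples drawn for each comparison over 19908 genes, only 1, the real one, gave as many genes. The real counts and the highest others were 5298 and 2388 with RL at 1 h, 12951 and 7394 at 3 h, 174 and 1 in water at 1 h and 2275 and 760 in water at 3 h. For the difference between the RL effects, other divisions of the experiment pairs between the times gave at most 487 against 7667. With the treatment shuffled within each time 2 of 100 were as large (highest 10539). Such shuffles can move the whole RL response into the difference, so chance is not excluded there. Only 16 splits part all 5 experiment pairs, too few to exclude chance for the other counts (highest others 1734, 6373, 0 and 760). The lists with the preset correlation were here adjusted over the 38 lists of a contrast and not over all 190 tests. With RL at 3 h 29 lists passed, the highest other split also gave 29, the median of the others was 20, and 4 of 100 were as large. Since another split tied with the real one, and this was the lowest such share among the 5 contrasts, chance is not excluded for the list counts. With an estimated correlation camera kept 0 of the 38 lists there (smallest adjusted p = 0.0542). With RL at 1 h 21 lists passed against a highest other of 26 (22 of 100 as large), for the difference 18 against 20 (7), in water at 1 h 12 against 22 (51) and in water at 3 h 26 against 28 (11).

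The first pattern weighed is the fall of all 14 root markers at 3 h. A lower share of root RNA in the RL samples stays open as a cause. Marker changes ran from -0.34 to -6.34, with an SD of 1.74, 9.89 times their median SE of 0.176. This spread cannot decide it, as the background may limit the largest falls, and root-only markers and equal loss of root tissues were not tested. The photosynthesis (shoot) list lay the other way at 3 h relative to all genes. Of its 33 genes 18 rose and 3 fell, and its median lay above that of all genes by 0.401, or 0.12 with quantile normalization, 0.401 with median scaling and 0.0853 in the deposited values of the authors, where 1, 26 and 0 rose. Dimmer arrays are argued against by quantile normalization, which left the median at -2.55. Whether root hair transcripts fall before those of the inner root stays open. At 1 h the median of 19 root hair genes lay below that of 14 endodermis and stele genes (difference -3.3), but the root hair list was drawn up after such genes were seen among the largest falls at 1 h, so it cannot test this. Damage to root cells stays open, untested.

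The second pattern is the rise of sulfur deficiency genes in water at 1 h, seen in a list of 15 chosen after the data were seen, of which 12 rose (median 2.07). Slide or scan date is argued against by medians of 2.19 and 1.88 within the scan dates and 1.94 with slide as a block, and a single experiment by medians over 0.3 in 5 of 5 experiments, from 1.49 to 2.49. A general shortage of nutrients after the start of treatment may explain it, since the median of 13 phosphate starvation genes was 1.1 with 7 up. In water at 3 h that list stood at 0.07 with 0 up by limma while 14 sulfur genes had risen, so the lists did not move together at both times. No untreated group was sampled at 1 h or 3 h, and ethanol, handling and time are not separated by the design.

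The third pattern is the excess of falls over rises at 3 h of RL. Whether the scaling point of the arrays makes it stays open. With the median of each array as the scaling point 46.0% of the changes of at least 2-fold were falls, 1755 against 2062 rises, but scaling to the median brings the median change of all genes to 0.0312 and so largely sets this balance itself. The excess stayed with quantile normalization, 8327 falls against 4455 rises past the threshold, and in the authors' values, 7989 against 4339, which does not settle where no change lies. A loss of plant RNA against the added spike-in RNA cannot be told apart from none: the spike-in signal relative to the 75th percentile was 0.025 higher with RL at 3 h, with an SE of 0.533 between arrays, 5 per group, each with the median of 7 probes (exact permutation p = 0.944). That SE keeps shifts of the size in question open.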

How the results depend on the processing

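The fits with normexp and quantile normalization, with normexp without spots of flagged local background, within each scan date and without a pair of samples apart from their groups, and the set tests with slide or scan date as a block or without CDPK-related kinases, were tests chosen after the results were seen.

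Within 1.5 times the reported value in all 6 counts (the 5 contrasts and the overlap of the RL calls) were those with quantile normalization, median scaling, the authors' deposited values, no filter, the filter on all 25 arrays, the mean of a gene's probes, the other variance model and scan date as a block. With the normexp background correction the counts were 1615 with RL at 1 h, 5934 at 3 h, 2826 for the difference, 26 and 184 in water at 1 h and 3 h, and 1116 for the overlap. Its fit followed a few spots far below their local background on 8 arrays, with a fitted background mean as low as -1350. Without flagged spots the means were 2.47 to 10.8 and the counts 4704, 11689, 5980, 126 and 1714. In water at 1 h the count was 115 with only the groups of the contrast, which leaves fewer samples, 279 and 275 with the experiment as a fixed or random term and 93 with slide as a block, where the cause was not tested.

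Stricter thresholds lowered counts by construction. With a 2-fold change required as well they were 1577, 3873, 2143, 38, 282 and 1370 in the order above, and with an adjusted p under 0.01 those of water were 86 and 862. With the fewer samples of a single scan date they were 2592 and 3278 with RL at 1 h, 3748 and 4854 for the difference, 37 and 18 in water at 1 h, 169 and 185 in water at 3 h, and 2272 and 2693 for the overlap. Leaving out 1 sample at a time gave 4626 to 5465 with RL at 1 h, 12392 to 12842 at 3 h, 6993 to 8096 for the difference, 109 to 172 in water at 1 h, 1283 to 3181 in water at 3 h and 3845 to 4504 for the overlap. Of the list shifts 4 of 190 passed with an estimated correlation, which widens the test of lists whose members move together, against 106. With fry 155 of the 190 list results kept their side of the threshold, and with slide as a block 180. Without the CDPK-related kinases that share the symbol CRK 106 list shifts passed, as before.

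Of 380 gene results named, 362 kept their direction and their side of the threshold with quantile normalization, 358 with median scaling, 354 with the authors' values, 360 with slide and 380 with scan date as a block, and 252 with normexp. Of the normexp fits, the one without spots of flagged local background kept 355 and the one with quantile normalization 359. The sign turned with normexp at 1 h of RL for CRT1b (0.037), AOX1D (-0.72), ATCAD4 (0.0111), DIN2 (-0.27), CRK31 (-0.46), CBF1 (-0.96), HSP21 (-1.07) and OMT1 (0.10). At 3 h it turned for PUB18 (0.38), WAKL1 (0.76), WAKL5 (0.63), JMT (0.70), PUB26 (0.28), LOX6 (0.11), P5CS1 (0.12), WRKY54 (0.0014), COR15A (0.14), PRR9 (0.61), LAG1 (0.33), AT4G10500 (0.58), PUB8 (0.18), DREB1A (0.21) and LCB2 (0.0341). In water it turned for AT1G19320 at 1 h (0.19) and AOX1D at 3 h (-0.68). None of these values passed, with adjusted p from 0.277 to 1. Without the spots of flagged local background 2 still turned, WAKL1 (0.051) and JMT (0.0271). Median scaling turned LCB2 at 3 h (0.0055), and the mean of the probes turned AT5G66400 (0.0114). With normexp the set test of the difference passed in the opposite direction for photosynthesis (adjusted p = 0.00886) and MYB factors (0.0343). Apart from the normexp values, the cause was not tested.

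Signal over background limits the low end. Between 69.43% and 77.54% of spots were well above background, and genes below it in every group were not tested.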

Other observations

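The lists in this part were chosen after the data were seen. Of 19 root hair genes 18 fell with RL at 1 h (median -3.57) and 18 at 3 h (median -4.95). The median at 3 h is the value of SHV2, which the background limits. Of 14 endodermis and stele genes 3 fell and 1 rose at 1 h (median -0.26), and 13 fell at 3 h (median -2.14). Of 15 sulfur deficiency genes 2 fell with RL at 1 h (median -0.19), and 11 rose and 2 fell at 3 h (median 0.95). Of 13 phosphate starvation genes 1 rose and 6 fell with RL at 1 h (median -0.61), and 1 rose and 7 fell at 3 h (median -0.46).

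Spike-in signal relative to the 75th percentile was 0.808 lower with RL than with water at 1 h (difference -0.808, exact permutation p = 0.183, 7 probes, 5 samples per group).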
